A study of Caenorhabditis elegans with 2 samples.

How the data were processed

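The series measured small RNAs bound to NRDE-3, an Argonaute protein that carries small RNAs to the nucleus of somatic cells in the nematode Caenorhabditis elegans. Per the labels' protocols, lysates of embryos from animals grown at 20 °C were incubated with anti-FLAG beads, and RNA eluted together with FLAG::GFP::NRDE-3 was cloned. The RNA was treated with an alkaline phosphatase and then with polynucleotide kinase, so that RNAs with 1 or several phosphates at the 5′ end could be ligated, and molecules of 20 to 30 nt were purified from a gel. There were 2 libraries. The wild-type library came from N2 animals fed OP50 bacteria. The RNAi library came from animals carrying mutations in eri-1 and dpy-13 and fed bacteria that express double-stranded RNA of dpy-13, and the study listed it as a control. Each group held 1 library, so no test of the conditions was possible and no p-value is given.

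The authors deposited raw counts of reads per transcript, in a sense and an antisense column. Per the series' design text, the authors aligned the reads to the WS243 transcriptome with Bowtie2 at default parameters and then counted the small RNAs for each gene. The version of Bowtie2 is not given in the sources used here. At default parameters Bowtie2 reports 1 alignment for a read that matches several places equally well, so counts of near-identical genes (histones, 5S ribosomal RNA, parts of the collagens) are uncertain for each member. The header line of each table had 5 names above lines of 6 fields, and the columns were taken by position. For the wild type 2 lines, and for the RNAi library 3 lines, lacked the second count and the class. They held 2 and 9 reads and were left out.

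The tables listed 56374 transcripts of 45510 genes, and isoform counts were added up per gene. Gene names, biotypes and coordinates came from the Ensembl 115 annotation of WBcel235, matched by gene identifier. Of the genes, 44852 matched and 658 did not. The tables themselves hold no coordinates, so every position given is that of the matched gene in this annotation and not that of the reads.

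The design, the thresholds, the rule for named genes and 18 gene lists were fixed before the data were examined. That plan assumed a single count per gene. Antisense reads were taken as the main measure because small RNAs that target a transcript are antisense to it, and this choice was made after the columns were seen. In both libraries over 99% of reads on microRNA genes were in the sense column (99.9% and 99.5%), so sense stands for the strand of the transcript. Levels are antisense RPM, reads per 1000000 counted reads of sense and antisense together. The wild-type library held 7693320 counted reads and the RNAi library 5537671. A count of 0 was treated as compatible with up to 3 reads, which is 0.390 RPM in the wild-type library and 0.542 in the RNAi library. Such floors and all intervals cover counting error only, since reads of amplified libraries without molecular identifiers are not independent molecules.

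Ratios are the RNAi library over the wild-type library, with the exact 95% interval that the binomial split of both counts gives (Clopper-Pearson). Log2 ratios had 0.5 added to each count, and a gene was measured when it had 10 or more antisense reads over both libraries. A gene met the size rule when it had 10 or more RPM in the higher library, a ratio of at least 4-fold and an interval wholly beyond 2-fold. For each gene list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 10 bins. The percentile describes these 2 libraries only. For lists of 2 or more measured genes the summed counts without the member of highest level were compared with random lists matched to the remaining members. The random lists kept their own highest gene, so these ranks do not compare like with like. That summed comparison was added after the list medians had been seen, as were 2 further lists, the type IV collagens and cuticle or molting genes other than collagens.

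Named genes were dpy-13, eri-1 and nrde-3, the 10 genes with the highest level in each library, the 10 genes per direction whose interval bound lay farthest from equal levels, and up to 4 members of each list. Genes of microRNA, ribosomal, transfer, small nuclear and small nucleolar RNA, called structural RNA here, were given as classes. The plan also asked for genes sharing stretches of sequence with dpy-13. No transcript sequences were used here, and the cuticle collagens, the family to which dpy-13 belongs, stood in as the plan provided.

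The code was tested on simulated counts for the comparison of the RNAi with the wild-type library over 5751 genes. It recovered 100% of 50 genes raised and 50 lowered by 6-fold, and 100% of as many changed by 16-fold, and called 0 unchanged genes. The intervals held the simulated ratio for 96.7% of genes. The simulated counts had counting error only, all other genes were kept at equal levels, and only genes well above the level minimum were changed. The test therefore checks the code, and does not show how often the rule errs on these 2 libraries.

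Alternatives were scaling with TMM (edgeR 4.0.16) and with median-of-ratios size factors (DESeq2 1.42.0) in R 4.3.3, leaving out structural RNA, other level and fold thresholds, the highest isoform in place of the sum, other pseudocounts and other minimum counts. Alternatives chosen after seeing the data were sense and antisense reads together, scaling to antisense reads outside structural RNA, scaling to microRNA sense reads with and without mir-260, each scaling applied to ratios with the level minimum unchanged, leaving out genes that overlap a gene on the other strand, and leaving out sqt-3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.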

Results

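The study asked which small RNAs NRDE-3 carries during normal growth, and whether nuclear RNA interference reaches genes other than its intended target. The data were 2 libraries of small RNAs bound to FLAG::GFP::NRDE-3 in embryos, 1 from wild-type animals and 1 from eri-1;dpy-13 animals fed dpy-13 double-stranded RNA. No replicate exists for either, so every difference given is between these 2 libraries, and genotype, food and library preparation cannot be separated. The wild-type library held 7693320 counted reads, of which 3429355 were antisense to a transcript, and the RNAi library held 5537671, of which 1227822 were antisense. Outside structural RNA the antisense reads numbered 1330907 and 425987, or 17.3% and 7.69% of counted reads. Ribosomal RNA sense reads made up 51.6% of the wild-type library and 68.2% of the RNAi library, or 78.6% and 78.7% with the reads on 4 genes annotated on the opposite strand of the ribosomal DNA.

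In wild-type embryos the antisense small RNAs bound to NRDE-3 fell on a small set of loci. The noncoding RNA T05E11.9 (chromosome IV, 11106418 to 11107579) had 167296 antisense reads, the long intergenic RNA linc-22 (chromosome X, 9069138 to 9073735) had 163886, and E01G4.5 (chromosome II, 13472401 to 13473995), a known target of the 26G small RNAs that the Argonaute ERGO-1 binds, had 95885. They were followed by F55C9.3 with 72007, H37A05.4 with 44294, the F-box gene fbxb-37 with 40425, F29G9.1 with 38413, linc-11 with 37542, C01A2.1 with 35705 and ZC132.4 with 34239. Together these 10 genes held 54.8% of the antisense reads outside structural RNA (Wilson 95% interval 54.7 to 54.9), and the top 100 genes held 96.5% (96.4 to 96.5).

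In the RNAi library a different set of genes led. The top gene was unc-119 (chromosome III, 10902641 to 10908935), a gene needed for neuronal development, with 98201 antisense reads, or 23.1% of those outside structural RNA. The next was nrde-3 itself (chromosome X, 372235 to 376900) with 10360. F23A7.4 had 4652, the transposon T27C5.9 had 4280, the cuticle collagen sqt-3 (chromosome V, 12352745 to 12354320) had 3994, got-1.2 had 3075, sqst-1 had 2228, F23A7.8 had 2220, T09F5.12 had 2133 and linc-29 had 2082. The top 10 genes held 31.3% (31.1 to 31.4) and the top 100 held 45.6% (45.5 to 45.8), so reads were less concentrated than in the wild-type library. Of the top 100 genes, 3 were in the top 100 of both libraries. With structural RNA kept, the top 10 held 77.9% and 73.2%, and 11 of the top 100 were shared. Across the 5751 measured genes the log2 levels had a Spearman correlation of 0.42 and a Pearson correlation of 0.28. Genes are not independent replicates, and among the 782 genes with 100 or more reads the Spearman correlation was −0.13. Both cut-offs are on the sum over the 2 libraries, a selection that by itself can lower a correlation.

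The first comparison checked the RNAi trigger and the strain genes. dpy-13 (chromosome IV, 4235614 to 4236710), a cuticle collagen gene, had 1 antisense read in the wild-type library and 115 in the RNAi library, or 0.130 and 20.8 RPM, a ratio of 160 (28.1 to 6365). Its sense reads were 8 and 47. In the RNAi library 447 genes outside structural RNA had more antisense reads than dpy-13. eri-1, the mutated exonuclease gene, had 2 and 10 antisense reads, a ratio of 6.95 (1.48 to 65.2), below the median of all genes, and under TMM scaling its log2 ratio was −0.42. nrde-3, whose tagged copy was present in both strains, had 319 and 10360 antisense reads, a ratio of 45.1 (40.4 to 50.6), beside 45147 and 46985 sense reads.

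Most other genes also had more antisense reads in the RNAi library. The median log2 ratio of the 5751 measured genes was 3.58, or 11.9-fold, with the middle of the distribution from 2.73 to 4.49, and 95.1% of measured genes had a ratio above 1. The size rule was met by 1069 genes in the higher direction and 151 in the lower direction, so 12.4% of the genes meeting it were lower. The higher count depended on the scaling. TMM brought the median to 0.37, with 9 genes higher and 162 lower (94.7% lower), and median-of-ratios size factors gave the same counts. TMM also raised the level minimum in the RNAi library from 55.4 to 513 reads. With that minimum unchanged, a setting chosen after seeing the data, 93 genes were higher and 162 lower (63.5% lower). Scaling to microRNA sense reads, also chosen later, gave 175 higher and 158 lower genes (47.4% lower), or 668 higher with the minimum unchanged, and without mir-260 it gave 44 and 159 (78.3% lower), or 221 higher. All these scalings shift every ratio down, so by construction none of them could remove a lower gene. Medians of gene groups are therefore compared with the median of 3.58. Calls by the size rule and all ratios remain relative to equal RPM, so a higher gene can still lie at or below that median. Of the 1069 higher genes, 98 lay 4-fold or more above it.

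**Figure D1:**
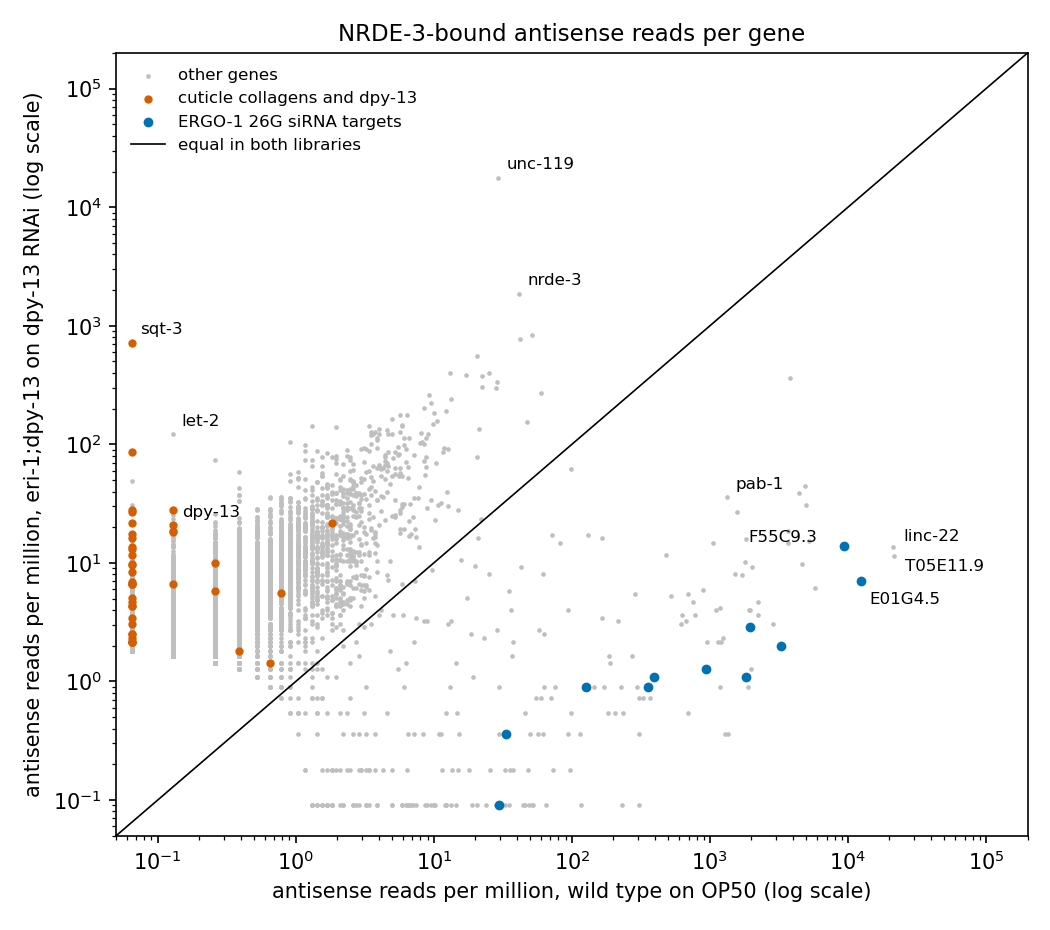
Antisense RPM of each measured gene outside structural RNA in the wild-type library (x axis, log scale) and the RNAi library (y axis, log scale), with genes at 0 drawn at the value of 0.5 reads. Points are single genes from 1 library each, blue points are the 11 ERGO-1 26G targets, all on the lower side, and orange points are the cuticle collagens and dpy-13, all on the higher side, while most genes lie above the line of equal levels, by a median of 3.58 on the log2 scale (0.37 under TMM).

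The genes with fewer antisense reads in the RNAi library were those that dominated the wild-type library. Outside structural RNA, 149 genes met the rule in the lower direction. They held 1292316 reads, or 97.1% of wild-type antisense reads outside structural RNA, against 5367 reads, or 1.26%, in the RNAi library, and their median log2 ratio was −7.34, a median of 162-fold lower. T05E11.9 was 1911-fold lower (1494 to 2488), E01G4.5 1770-fold lower (1294 to 2489) and linc-22 1573-fold lower (1255 to 2000). F40H3.6 went from 10403 reads to 2, a ratio of 3744-fold lower (1036 to 30920), and Y17D7B.4 from 9907 to 2, a ratio of 3566-fold lower (987 to 29446). Y37E3.30 was 2080-fold lower (891 to 6407), C40A11.10 1678-fold lower (771 to 4573), W04B5.2 1646-fold lower (920 to 3299), the transposon T16A1.9 1559-fold lower (757 to 3879) and H37A05.4 938-fold lower (671 to 1354). By class, 124 of the 149 genes were listed as protein-coding, 13 were long intergenic RNAs out of 37 measured, 9 were other noncoding RNAs and 3 were transposons. The current annotation calls 14 of them pseudogenes. Of the 151 lower genes in all, 20 overlap a gene on the other strand.

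All 11 matched ERGO-1 26G targets were in this group. Their summed antisense reads were 236546 in the wild-type library and 174 in the RNAi library, and their median log2 ratio of −9.37 lay below all 10000 random lists, whose lowest median was −8.19. F55C9.3 was 673-fold lower (539 to 853) and Y37E11B.2 681-fold lower (419 to 1192). Sense reads on the same genes numbered 368 and 262. Another 3 names of the list were not matched and were not analysed here.

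Among the genes with the largest excess in the RNAi library were collagens. Of the 176 cuticle collagens, the exoskeleton proteins to whose family dpy-13 belongs, 40 were measured, 14 met the size rule in the higher direction and 0 in the lower direction. sqt-3 went from 0 to 3994 reads, at least 1850-fold higher. col-34 (chromosome IV, 4243545 to 4244610), a neighbour of dpy-13, went from 0 to 480, at least 222-fold higher, and col-3 from 0 to 156, at least 72.2-fold higher. dpy-14 had 1 and 154 reads, a ratio of 214 (37.8 to 8505). The list's median log2 ratio was 6.42, above all 10000 random lists, whose highest median was 4.71. In 30 of the 40 genes 1 library had no read, and with those genes set at the floor the median was 4.12, or 0.84 above the all-gene median computed in the same way. With all 112 collagens of 1 or more reads the median was 3.28, against 2.80 for all genes taken in that way. Summed over the list, antisense reads were 46 and 6674, 202-fold higher (151 to 276). Without sqt-3 they were 46 and 2680, 80.9-fold higher. For the 39 measured genes without sqt-3 the sum was 95.8-fold higher (69.0 to 137), above 9952 of 10000 random lists, which kept their own highest gene. Under TMM the list median was 3.21 and remained above 0. The summed sense reads of the list had a ratio of 3.46.

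The other genes with the largest excess were not of 1 family. unc-119 was 609-fold higher (534 to 697), from 224 reads. The type IV collagens of basement membranes, a list added later, gave let-2 with 1 and 678 reads, a ratio of 942 (168 to 37258), and emb-9 with 0 and 271, at least 125-fold higher. unc-44, an ankyrin gene, was 110-fold higher (59.5 to 230), Y54G2A.40 was 285-fold higher (78.3 to 2360), and ckk-1 and the pseudogene F56H1.3, both at 0 in the wild-type library, were at least 78.7-fold and 73.2-fold higher. The 9 genes that were higher under RPM, TMM and median-of-ratios scaling, the last 2 with their raised level minimum, were unc-119, nrde-3, sqt-3, Y110A2AL.1, unc-44, B0001.5, let-2, pxd-1 and tln-1, of which Y110A2AL.1, B0001.5, pxd-1 and tln-1 were named after their values were seen.

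**Figure D2:**
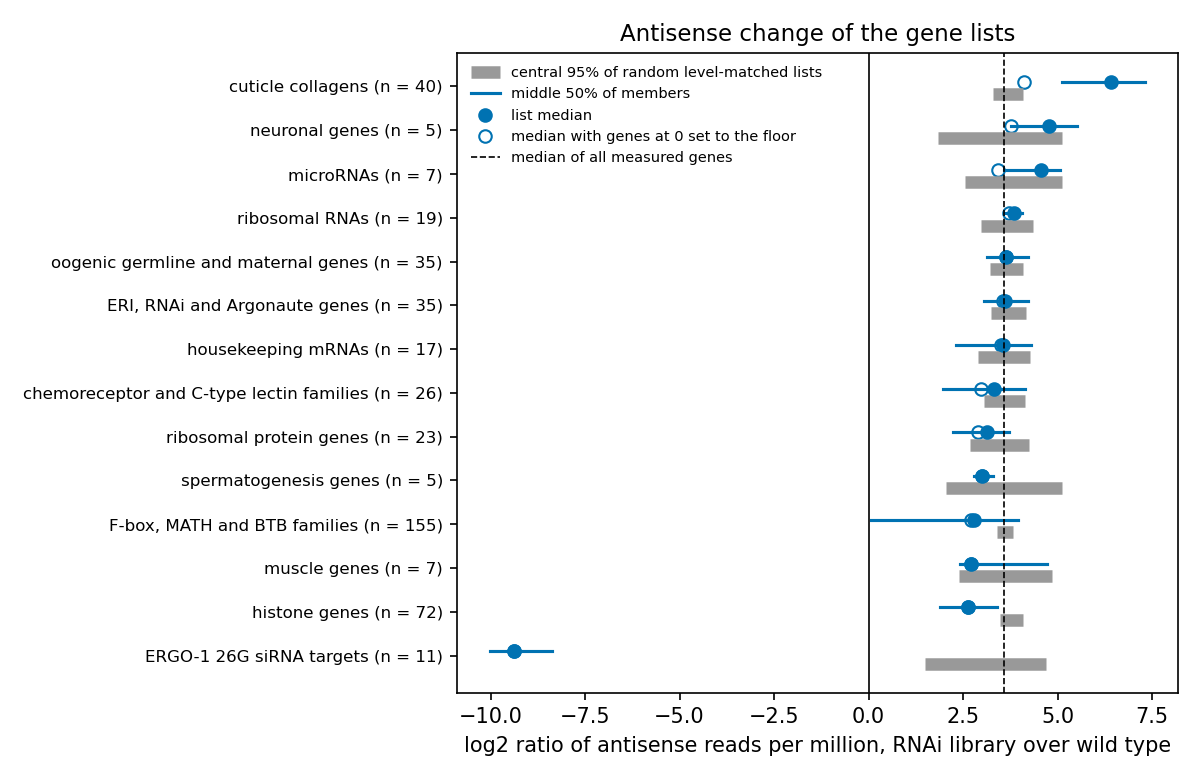
Median log2 ratio of antisense RPM, RNAi over wild-type library, for each gene list with 5 or more measured genes (filled circles, with lines for the middle of the members' distribution, and open circles for medians with genes at 0 set to the floor). Grey bars give the central 95% of 10000 random level-matched lists and the dashed line the all-gene median of 3.58. The cuticle collagens lie to the right at 6.42 and the ERGO-1 targets to the left at −9.37, and under TMM all values shift left by 3.21, which takes the F-box, histone, muscle, ribosomal protein and spermatogenesis medians below 0.

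The medians of gene groups of the germline and of RNA interference lay near that of all genes. Of 35 measured ERI, RNAi and Argonaute genes 14 met the size rule, all in the higher direction (40%, against 18.6% of all measured genes). Their median of 3.60 lay at the 37.8th percentile of random lists. Relative to the all-gene median, 5 of the 35 were 2-fold or more above it and 2 were 2-fold or more below. Another 3 names of this list were not matched. eri-12, which is outside the list and was chosen after its values were seen, had 2343 and 4 reads, 422-fold lower (164 to 1549). hrde-1, a germline nuclear Argonaute, was 38.9-fold higher (18.5 to 98.0) and eri-6 12.9-fold higher (10.0 to 16.9). Of 35 measured oogenic and maternal genes 5 met the rule (14.3%), and their median was 3.64, at percentile 44.1. rme-2, the yolk receptor, had 2 and 76 reads. The 17 measured housekeeping genes had a median of 3.55 and the 26 chemoreceptor and lectin genes 3.32, at the 41.8th and 18.4th percentiles. The last list was taken by name and also holds src-1, a kinase gene, with 16 and 175 reads.

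The medians of histone and F-box genes lay below that of all genes. The 72 measured histone genes had a median of 2.62, below all 10000 random lists, whose lowest was 3.20. Of them, 36 were 2-fold or more below the all-gene median and 2 were 2-fold or more above it. By the size rule 30 of the 72 were higher (41.7%) and 1 lower. Near-identical histone copies share reads, and under TMM the median was −0.59. The distance from all genes depended on the setting. With 5 added to each count the histone median was 2.17, against 2.32 for all genes. With 1 or more reads it was 2.69, against 2.80, and with 100 or more reads 3.04, against 3.81. Of 155 measured F-box, MATH and BTB family genes, which encode substrate adaptors of ubiquitin ligases, 23 were higher and 17 lower by the size rule, and their median of 2.80 lay below all random lists, whose lowest median was 3.15. fbxb-37 was 342-fold lower (277 to 429) and fbxa-52 262-fold lower (72.2 to 2165), while fbxb-97 was 18.4-fold higher (14.6 to 23.4) and bath-45 had 36 and 474 reads. Under TMM the median of this list was −0.42.

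Lists of other tissues and of RNA classes were small. The 7 measured muscle genes had a median of 2.71, at the 6.50th percentile. Over all 20 muscle genes of the list, measured or not, the summed reads were 17 and 125, 10.2-fold higher (6.13 to 18.1). The 5 neuronal genes had a median of 4.77, at the 92.5th percentile, and besides unc-119 only unc-10 met the size rule, at 27.8-fold higher (18.6 to 43.4). The 23 ribosomal protein genes had a median of 3.14 and the 5 spermatogenesis genes 3.01, at the 11.5th and 30.8th percentiles, and 0 met the size rule in either list. No intestinal gene reached 10 reads, and the sums of that list were 10 and 9 reads. piRNAs had 0 and 4 antisense reads. The 7 microRNA genes with enough antisense reads had a median of 4.56, at the 89.3th percentile. Sense reads on microRNAs, which other Argonautes bind, were 3.45-fold higher in sum, and 6.75-fold higher without mir-260, which had 11040 and 4 reads.

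Summed reads without the top member of each list did not always rank as the medians did. Random lists kept their own highest gene and could include lowered genes with many wild-type reads. Their median summed ratio was 0.527 for the histone size and level. It was 0.481 for the F-box, MATH and BTB list, 1.00 for ribosomal RNAs and 1.57 for ERI, RNAi and Argonaute genes. For cuticle collagens it was 2.35, but for oogenic genes 10.1. Ranks are therefore not comparable between lists, and a high rank can go with a ratio near the all-gene median of 11.9-fold. The histones' sum was 4.89-fold higher (4.63 to 5.18), above 9105 of 10000 random lists. That of F-box, MATH and BTB genes without fbxb-37 was 1.38-fold higher (1.33 to 1.42), above 7480. With fbxb-37 the whole F-box, MATH and BTB list had 47418 and 7289 antisense reads and was lower in the RNAi library, at a ratio of 0.214 (0.208 to 0.219). The sum of ERI, RNAi and Argonaute genes was 13.2-fold higher (11.5 to 15.3), above 9137, and that of oogenic genes 14.01-fold higher (11.5 to 17.3), above 8986. The other values were 57.9-fold for strain genes (above 9501), 27.4-fold for neuronal (8693), 12.4-fold for ribosomal RNAs (8540), 14.97-fold for microRNAs (7097), 9.79-fold for ribosomal proteins (5960), 10.6-fold for muscle (4990), 10.2-fold for housekeeping (4947), 4.04-fold for chemoreceptor and lectin (2332) and 6.25-fold for spermatogenesis genes (2275). The ERGO-1 targets lay below all random lists. Cuticle and molting genes other than collagens, a list added later and taken by name, had 8 of 27 higher. Their median was 4.04, at the 94.8th percentile, and their sum 8.07-fold higher, above 3030. Of those 27, 16 were pqn genes, named for prion-like glutamine- and asparagine-rich stretches, or abu genes. Under TMM all these ratios shift by −3.21 on the log2 scale, which takes the sums of histones, F-box, chemoreceptor and lectin, spermatogenesis and these cuticle genes below 1.

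Ribosomal RNA was given as a class. Most reads counted as antisense to it were on 4 genes annotated on the opposite strand inside the ribosomal DNA repeat, which held 98.9% and 73.4% of such reads, so these match the strand of the ribosomal RNA itself. Another 3 genes of the 5S repeats had 20728 and 190324, with few sense reads, so these may also match the strand of the 5S RNA. Of these, rrn-4.3 (6786 and 63429) and rrn-4.4 (6779 and 59526) held most reads behind the 12.4-fold sum of the ribosomal RNA list. That sum is therefore not a clear antisense change. The other 17 genes had 2718 and 21976 antisense reads, or 353 and 3968 RPM, 11.2-fold higher (10.8 to 11.7), close to the all-gene median of 11.9-fold.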

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

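The tests weighed here were all chosen after the values had been seen. For the collagens a first form of the tests compared medians of the lists, and the form given here, on summed reads, replaced it because most collagens had no read in the wild-type library. Results of both forms are given. The test of the freed share first compared the points of counted reads gained by other genes (7.09) and lost by lowered ones (16.7), which ignored that freed reads raise all others alike. The tests on neuronal genes and on neighbours were also restated, since their first forms, a difference of −3.73 between egl-21 (0 and 16 reads) and unc-119 and a highest neighbour count of 228, could not decide.

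Reads in the sense column, which the main measure left out, were high on a few protein-coding genes. nrde-3 had 45147 sense reads in the wild-type library and 46985 in the RNAi library, or 17.97% and 10.7% of all sense reads on protein-coding genes. In the wild-type library the gene WBGene00194913 had 5398 sense reads, against 38 in the RNAi library, and W05H12.4 had 4639, against 22. W05H12.4 overlaps W05H12.2 on the other strand, which had 8045 antisense reads in the wild-type library, so both counts concern small RNAs of 1 strand. In the RNAi library sma-5 had 7825 sense reads, Y46H3D.8 had 7116 and elt-1 had 3641, against 7, 0 and 25 in the wild-type library. All lie far above the floors of 0.390 and 0.542 RPM.

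The first pattern is that antisense reads were higher against most genes in the RNAi library, by a median log2 ratio of 3.58. A larger carry-over of RNA that NRDE-3 does not bind, alike for all small RNAs, would give an equal excess of microRNAs, but the antisense median exceeded that of 55 microRNAs by 1.27 on the log2 scale (microRNA median 2.31, 95% resampling interval 1.97 to 2.75). This difference was computed in the main setting only. The all-gene antisense median was 2.80 with 1 or more reads and 2.32 with 5 added to each count. Other reads not expected from antisense targeting rose too, many of them by less than 11.9-fold. Sense reads were 5.51-fold higher in sum for transfer RNA and 4.82-fold for small nucleolar RNA, and by a median of 2.74-fold for protein-coding genes. Reads on the 3 genes of the 5S repeats, which may be 5S RNA itself, rose as much as the antisense median, by 12.2-fold to 13.1-fold. The antisense share of reads outside structural RNA fell from 83.6% to 48.3%. That fall lies on the lowered genes, which held 97.1% of these antisense reads in the wild-type library, and says nothing on the genes that rose. Antisense reads on all other genes outside structural RNA went up, from 0.502% to 7.60% of counted reads. As reads not expected from antisense targeting rose too, a part played by carry-over stays open. Carry-over that differs between kinds of small RNA was not tested. A share of the sequenced reads left free by the lowered genes, if it raised all other reads alike, would do so by 1.36-fold. The lowered genes here include F31C3.16, 1 of the 4 opposite-strand genes of the ribosomal DNA. Outside structural RNA the factor was 1.20-fold. The median of 11.9-fold (resampling interval 11.58 to 12.1) was 8.80 times the factor of 1.36, which argues against a rise alike in all reads as the whole cause. Ribosomal RNA with those 4 genes kept its share, however (78.6% and 78.7%). A freed share taken up only by other reads would give a larger factor, which was not computed. The biological difference in the design, loss of eri-1 together with the feeding of double-stranded RNA, stays open and untested, as does the loading of other small RNAs onto NRDE-3 in place of the lost ones.

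The second pattern is the excess of antisense reads on cuticle collagens. Older embryos in which all differentiated tissues rose alike would raise muscle genes as much. Without sqt-3 the summed collagen ratio of 80.9 (resampling interval over genes 40.1 to 205) was 7.92 times that of muscle genes (10.2, 5.61 to 24.4). The summed sense reads of both lists had similar ratios (3.46 and 3.42). This argues only against a rise equal in muscle, which had 17 wild-type reads. The neuronal genes without unc-119 were 27.4-fold higher in sum (18.7 to 41.6, counting error only), which reaches the collagen interval. Older embryos with a rise that differs between tissues stay open and were not tested. A rise of all cuticle-making tissue stays open. The collagen ratio was 10.1 times that of cuticle and molting genes other than collagens, and 21.1 times without the pqn and abu genes in that list. On medians with genes at 0 set to the floor, though, the intervals overlapped (3.50 to 4.93 and 2.70 to 4.30). In the first form, on medians, the differences from the collagens were −3.71 for muscle and −2.38 for the other cuticle genes. The collagens were thus higher in that form (5.47 to 6.95, against 3.01 to 4.87 for the other cuticle genes), but it depends on genes with no read. Small RNAs spreading from dpy-13 through sequence shared among collagens stay open: shared stretches were not measured, and the type IV collagens (emb-9 at least 3.39 above the all-gene median on the log2 scale) say nothing on it, since their list was added after they had been seen among the highest genes. The mutation in dpy-13 and the feeding of its double-stranded RNA cannot be separated here.

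The third pattern is that unc-119 and nrde-3 led the RNAi library. More neuronal RNA would raise other neuronal genes, but the 4 other measured ones together had 28 and 552 reads, 27.4-fold higher (18.7 to 41.6), or 23.6-fold (7.64 to 118) without unc-10, which held 501 of these reads, against 609-fold (534 to 697) for unc-119. Silencing aimed at transgene copies is a candidate explanation, since nrde-3 was present as a tagged transgene and unc-119 is widely used as a marker in worm transgenes. Whether these strains carry an unc-119 marker is not given in the sources used here. Genes within 20 kb do not decide between such copies and the native genes, since 12 neighbours of nrde-3 were 24.6-fold higher in sum (16.3 to 38.8), above the all-gene median of 11.9-fold and below nrde-3 at 45.1-fold (40.4 to 50.6), with R04A9.7 at 9 and 228 reads, and 5 neighbours of unc-119 had only 3 and 42 reads.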

How the results depend on the processing

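Settings chosen after seeing the data are named so. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out in turn. TMM, median-of-ratios and microRNA scaling shift every ratio down, so by construction they could not remove any of the 151 lower genes. Scalings that shift ratios up kept, of the 149 outside structural RNA, 145 without structural RNA and 140 relative to antisense reads outside structural RNA. The lower count stayed within 1.5 times of 151 except at a minimum of 50 RPM (98). The higher count of 1069 was 9 under TMM and 9 under median-of-ratios factors, 4829 without structural RNA, 153 at 50 RPM and 4861 with no level minimum. Among settings chosen later it was 1835 with sense and antisense reads together, 6539 relative to antisense reads outside structural RNA, 175 and 44 when scaled to microRNA sense reads with and without mir-260, and 709 without genes overlapping a gene on the other strand. Scaling also moves the level minimum in reads. With that minimum unchanged, a setting chosen later, the higher count was 93 under TMM, 97 under median-of-ratios factors, 668 and 221 under microRNA scaling with and without mir-260, 1072 without structural RNA and 1083 relative to antisense reads outside structural RNA, so the last 2 stayed within 1.5 times of 1069. Leaving out dpy-13, a 2-fold or 8-fold threshold and the highest isoform kept both counts within 1.5 times.

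Under TMM and median-of-ratios factors, in this order, the log2 ratio of dpy-13 was 4.108 and 4.12 against 7.32 from the counts, that of nrde-3 2.28 and 2.29 against 5.50, and the summed ratio of the cuticle collagens 4.44 and 4.45 against 7.66, while eri-1 turned to −0.42 and −0.41. Medians of lists that kept their sign were the strain genes 2.28 and 2.29, cuticle collagens 3.21 and 3.22, ERGO-1 targets −12.58 and −12.57, ERI, RNAi and Argonaute genes 0.39 and 0.39, oogenic genes 0.43 and 0.44, neuronal genes 1.56 and 1.57, chemoreceptor and lectin genes 0.11 and 0.12, microRNAs 1.35 and 1.36, ribosomal RNAs 0.64 and 0.65 and housekeeping genes 0.34 and 0.34. Medians that turned below 0 were spermatogenesis genes −0.20 and −0.19, histones −0.59 and −0.58, ribosomal proteins −0.075 and −0.067, muscle genes −0.50 and −0.49 and F-box, MATH and BTB genes −0.42 and −0.41. The cause lies in the shift that both scalings apply to every gene. Without structural RNA the ratio of nrde-3 was 5.87 and the histone median 3.00. Leaving out dpy-13 took the median of the strain genes, of which it is 1, to 4.02. Without sqt-3 the collagen sum was 6.34.

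With 5 added to each count the medians that left their 95% resampling interval or shifted by over 1.5-fold were the strain genes 4.80, cuticle collagens 3.54, ERGO-1 targets −8.75, ERI, RNAi and Argonaute genes 2.73, oogenic genes 2.54, spermatogenesis genes 1.80, histones 2.17, ribosomal proteins 1.89, muscle genes 1.89, neuronal genes 2.54, F-box, MATH and BTB genes 1.93, chemoreceptor and lectin genes 2.06, microRNAs 2.52, ribosomal RNAs 2.83 and housekeeping genes 2.06. With 100 or more reads per gene they were the strain genes 6.12, cuticle collagens 8.39, ERI, RNAi and Argonaute genes 4.14, histones 3.04, neuronal genes 7.01, F-box, MATH and BTB genes 0.69 and housekeeping genes 4.29. With 1 or more reads they were cuticle collagens 3.28, spermatogenesis genes 2.06, ribosomal proteins 2.59, neuronal genes 2.43, F-box, MATH and BTB genes 2.22, chemoreceptor and lectin genes 2.06 and microRNAs 2.06. The all-gene median moved as well, from 3.58 to 2.32 with 5 added, 3.81 with 100 or more reads and 2.80 with 1 or more reads. Medians in each setting are to be read against it, and with 5 added it fell along with every positive list median. Of the 40 cuticle collagens 30 had no read in 1 library, so their median follows the number added. For the other lists the cause of their own shift was not tested. The Spearman correlation turned to −0.13 with 100 or more reads per gene, and was 0.49 with the lowered genes left out. Selecting genes on reads summed over both libraries can by itself lower it. Without structural RNA the top 10 and top 100 genes held 54.8% and 96.5% of antisense reads in the wild-type library and 31.3% and 45.6% in the RNAi library. Stretches of 16, 20 or 25 nt shared with dpy-13 were not run. Depth limits statements on single genes below 10 reads, such as the intestinal list.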

Other observations

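The test of clustering in this part was chosen after the result was seen.

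Long intergenic RNAs stood apart from other classes. Of 37 measured, 13 were lower and 8 higher in the RNAi library by the size rule, and their median log2 ratio was −5.02, against 3.64 for protein-coding genes and 3.41 for 176 transposons. linc-16 was 940-fold lower (587 to 1615), linc-12 490-fold lower (324 to 782), linc-68 1316-fold lower (564 to 4053) and linc-17 528-fold lower (302 to 1023). These genes were named after their values were seen. Among transposons 40 were higher and 3 lower, with T25G12.8 284-fold lower (189 to 448) and Y60A3A.27, the transposon with most reads, 10.6-fold lower (10.1 to 11.09). pab-1, which encodes a poly(A)-binding protein, was 37.1-fold lower (32.2 to 42.9).

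The lowered genes lie close together on the chromosomes. Of 143 lowered genes with a position, 79 were within 20 kb of another lowered gene, against a median of 12 and at most 28 in 2000 random draws of as many measured genes, so chance placement among measured genes is unlikely. Without genes that overlap a gene on the other strand it was 65 of 123, against a median of 10 and at most 26. Gene families arranged in tandem may share reads or sequence, which was not tested. By chromosome, 1.14% of measured genes on I, 2.60% on II, 2.75% on III, 1.62% on IV, 4.31% on V and 4.22% on X were lowered, and differences between chromosomes were not tested.

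microRNA sense reads also differed between the libraries. mir-260 had 11040 reads in the wild-type library and 4 in the RNAi library, while 4 others had more in the RNAi library, with mir-228 19.3-fold (17.5 to 21.3), mir-57 8.79-fold (8.37 to 9.23), mir-35 8.25-fold (7.74 to 8.79) and mir-82 5.12-fold higher (4.90 to 5.36). All 5 were chosen after their values were seen.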
